A study of Mus musculus with 12 samples.

How the data were processed

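RNA from Percoll-isolated kidney proximal tubules of mice aged 20 weeks was hybridized to 12 Affymetrix mouse arrays, 1 per sample. The labels give 4 groups of 3 samples: wild type, catalase-Tg, dB/dB and dB/dB catalase-Tg. The samples of a group are numbered 1 to 3 in the labels, which do not say that they came from separate animals, so p-values measure the spread between these samples, which may be technical. The labels give no sex, and no batch or scan date was used here.

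The deposited values are log2 expression per probe set. They were made by the authors with GCRMA, a background correction and normalization between arrays, and limma is also named, both per the submitters' processing notes, which give no versions in the sources used here. The values ran from 2.302, a floor at which many probe sets lay, to 15.66. No further normalization was applied. The number of arrays limits the precision.

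Of 45101 probe sets, 64 array controls were left out of the tests. In GEO's annotation of the array, 34945 of the remaining 45037 probe sets had 1 gene symbol, 932 had several and 9160 had none. No gene was named from a probe set with several, and probe sets without a symbol are reported as such. Symbols were looked up through their gene identifiers in the NCBI RefSeq gene table of GRCm38.p6, which updated 0 of them, and no coordinates from it are printed. The 9744 genes tested were represented by the probe set with the highest mean over all 12 arrays.

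Probe sets above 4 (log2) on at least 3 of the 12 arrays were tested, 18144 in all. Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group and all 12 arrays in a single fit, default empirical Bayes settings, Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The 7 contrasts were dB/dB against wild type, catalase-Tg against wild type, dB/dB catalase-Tg against dB/dB, dB/dB catalase-Tg against catalase-Tg, their interaction, and the average effect of either factor over both states of the other. Standard errors (SE) are those of the moderated test and standard deviations (SD) those of the 3 arrays of a group.

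Lists of genes for kidney pathways and for markers of other cell types that isolated tubules can hold, 32 in all, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 32 lists within a contrast. Of 751 list entries, 674 matched a gene named on the array. Each call is given with the adjusted p from a correlation estimated from the data, and fry was run beside it. Counts of list members past the threshold are given over all probe sets and adjusted over the list alone. A list's score on an array is the mean difference of its members from their mean over the 12 arrays.

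The genes named follow a rule. It takes Cat and Lepr; per contrast against wild type or against dB/dB, up to 8 genes rising and 8 falling most past the threshold without overlap of the groups; up to 4 members with the smallest p of each list discussed; Casp12, Bmf, Agt, Tgfb1, Hmox1 and Kap, on which work on this mouse model has centred; up to 8 genes moved back by the transgene in each direction; and up to 8 with the smallest p in the interaction. Genes past the threshold in the other 3 contrasts, probe sets without a symbol, Smarce1, the sex-linked genes and the genes of single arrays were named after their values had been seen.

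The groups, contrasts, filter, lists, naming rule and the alternatives for filter, spread estimate, array weights, normalization, probe sets per gene, samples in the fit, fold minimum, replicate number as a block and leaving out each array were fixed before the data were examined. Other alternatives were added after seeing the data: a covariate from the podocyte, endothelial and mural marker scores, the set of wild type 1, catalase-Tg 1 and dB/dB catalase-Tg 1 left out, wild type 2 and wild type 3 left out, and array weights in the list test or with that covariate. Those 3 arrays were picked because limma gave them low array weights, which follow the arrays' own distance from their groups. A range over all alternatives covers only the fits in which that result was computed. For single genes it leaves out the other filters, 1 probe set per gene, the fold minimum and array weights with the covariate. For lists it leaves out the stricter filter, the other spread estimate, the other normalizations, the groups of the contrast alone, the fold minimum and array weights with the covariate.

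The tests were tested on simulated data with the spread of these arrays and independent noise between probe sets, unlike the correlated values of real arrays. For dB/dB against wild type, with 18144 probe sets, 14% of probe sets changed 2-fold were called, 76% of those changed 4-fold, 76% at 8-fold and 92% at 16-fold, and 6 unchanged probe sets were called. For the average dB/dB effect the shares were 42%, 88%, 86% and 94%, with 8 unchanged probe sets called. For dB/dB catalase-Tg against dB/dB, simulated without a change, 0 were called. A list shifted by 1 (log2) was called, with 0 of the 31 other lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.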

Results

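Gene expression was measured in proximal tubules, the nephron segment that reabsorbs most of the filtered glucose, amino acids and phosphate, from mice of 4 groups with 3 arrays each. dB/dB mice lack a working leptin receptor and become obese and diabetic. The second factor was a catalase transgene, catalase being the peroxisomal enzyme that breaks down hydrogen peroxide, carried by otherwise wild-type mice (catalase-Tg) and by dB/dB mice (dB/dB catalase-Tg). Between 36.9% and 38.5% of probe sets lay above 4 (log2) on an array. Median values ran from 2.63 to 2.82, and the highest from 15.36 to 15.66. Arrays of a group correlated at r = 0.941 to 0.996 across all probe sets, and arrays of different groups at 0.938 to 0.991.

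Catalase and the leptin receptor were looked at first, as the genes that define the groups. Catalase signal was high in every group. The brighter of 2 Cat probe sets read 11.92 ± 1.10 (SD, n = 3) in wild type, 12.27 ± 0.24 in catalase-Tg, 12.39 ± 0.16 in dB/dB and 12.44 ± 0.59 in dB/dB catalase-Tg. The transgene difference was 0.34 (log2, SE 0.48, adjusted p = 0.843) without dB/dB and 0.06 (SE 0.48, adjusted p = 0.972) with it, and neither passed. The second probe set gave 0.44 (SE 0.57) and 0.68 (SE 0.57). The 0.68 passed with array weights, at a size of 0.98 (adjusted p = 0.0121) and without wild type 1, catalase-Tg 1 and dB/dB catalase-Tg 1 (1.10, adjusted p = 0.00945), in a range of 0.00945 to 1.00 over all alternatives. Without those 3 arrays this probe set also passed in dB/dB against wild type (-0.73, adjusted p = 0.0383, in a range up to 1). The brighter one passed in catalase-Tg against wild type without wild type 2 and wild type 3 (1.60, adjusted p = 0.0403, in a range up to 1). Leaving out wild type 1, catalase-Tg 1 and dB/dB catalase-Tg 1 leaves wild type with wild type 2 and wild type 3, the arrays that carry Xist, a transcript of female cells. Cat on wild type 1 was 10.66, below the other 2 wild-type arrays at 12.68 and 12.43, and without wild type 1 the first transgene difference was -0.29. From work on these mice, not from the labels, the transgene is a rat catalase sequence driven by the promoter of the kidney androgen-regulated protein gene Kap, so these mouse probe sets do not check the labels. All 4 Lepr probe sets lay near the floor, with group means of 2.302 to 2.546, below the filter, and check nothing either.

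Markers of other kidney cells differed between arrays of the same group. The score of 16 endothelial markers was 1.55 on wild type 1, -1.45 on wild type 2 and -0.05 on wild type 3, and 1.55, -0.82 and -1.18 on dB/dB catalase-Tg 1, 2 and 3. It lay at 1.44, 0.88 and 1.81 on the dB/dB arrays and at -0.11, -1.92 and -1.71 on the catalase-Tg arrays. Proximal tubule genes ran the other way, with scores of -1.93 on wild type 1 and 0.84 on wild type 2. Wild type 1 correlated best with the dB/dB arrays (mean r = 0.987, against 0.954 with its own group), as did dB/dB catalase-Tg 1 (0.983 against 0.961). The other 4 arrays of these 2 groups correlated best with catalase-Tg: wild type 2 (0.984 against 0.963), wild type 3 (0.982 against 0.976), dB/dB catalase-Tg 2 (0.985 against 0.978) and dB/dB catalase-Tg 3 (0.984 against 0.978). Kap, an abundant androgen-responsive transcript of the proximal tubule, read 8.63, 11.70 and 15.23 on the 3 wild-type arrays and 8.46, 15.26 and 15.22 on the catalase-Tg arrays.

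**Figure D1:**
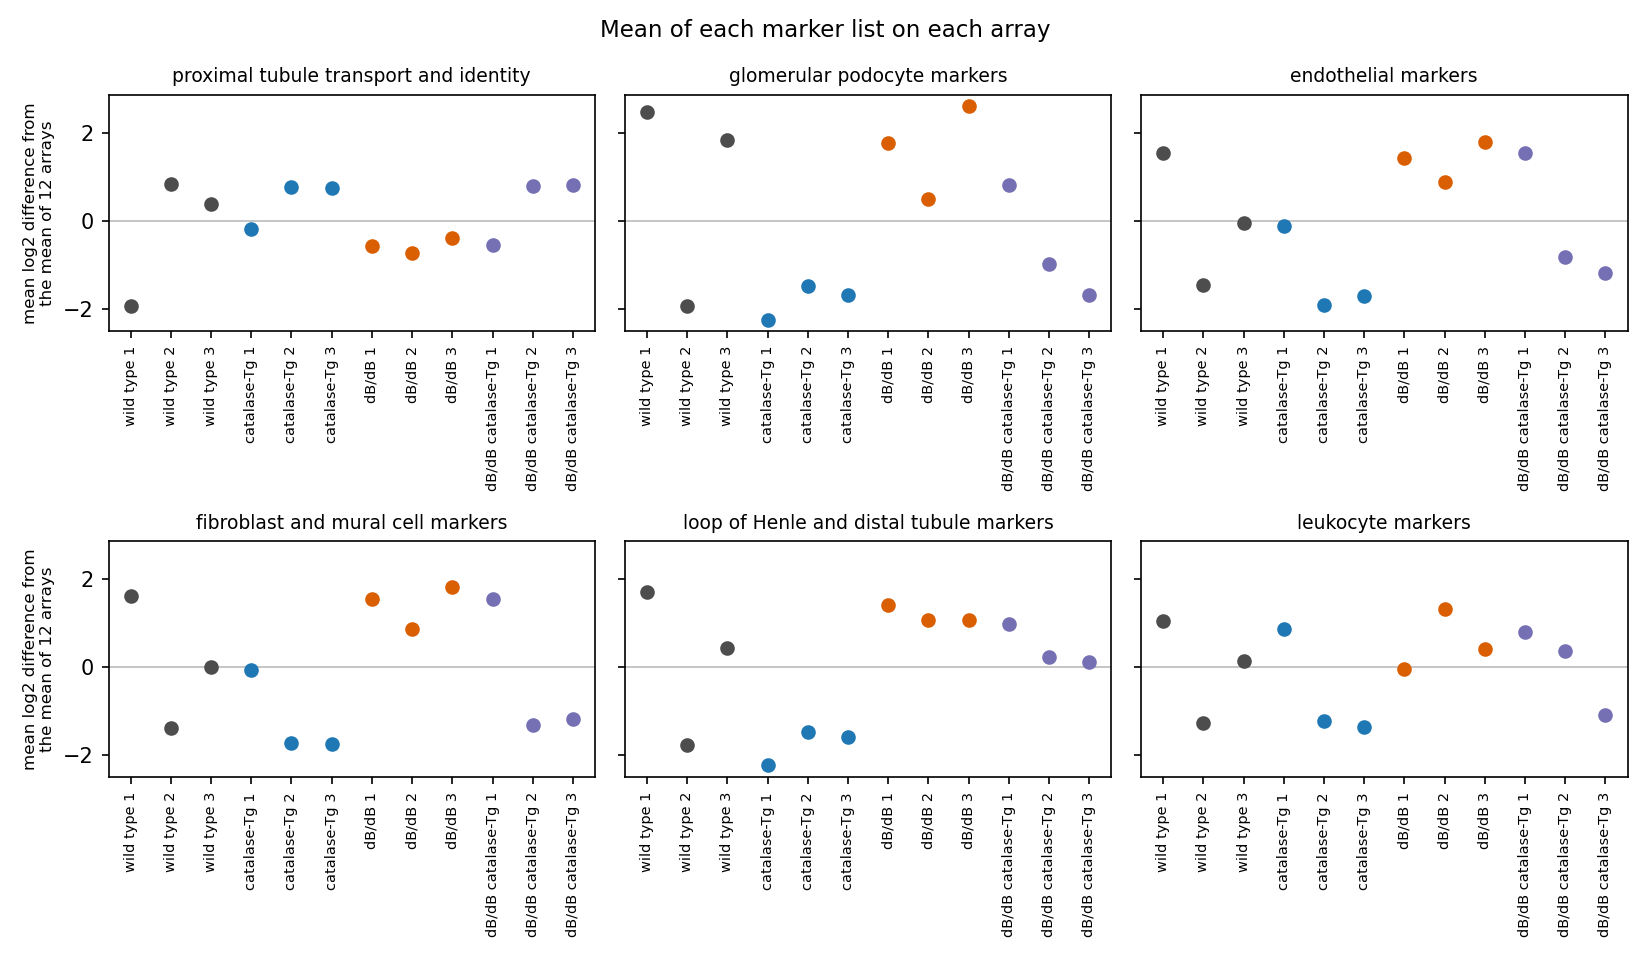
Mean log2 difference of each gene list from the mean of the 12 arrays, 1 point per array, coloured by group, for proximal tubule genes and for 5 lists of markers of other cells. Endothelial scores run from 1.55 to -1.45 within wild type, while the 3 dB/dB arrays lie between 0.88 and 1.81.

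What the leptin receptor mutation does to tubule expression is addressed by dB/dB against wild type. No single gene passed, and lists of endothelial, collecting duct and mural cell genes lay higher and lipid synthesis genes lower in 1 list test only (each with adjusted p = 0.628 with an estimated correlation). Without wild type 2 and wild type 3 these calls ended (adjusted p = 0.987, 0.629 and 0.85, the mural list turning direction, and 0.326 for lipid synthesis), and wild type 1 itself scored 1.55 on endothelial genes, above dB/dB 1 and dB/dB 2 at 1.44 and 0.88. Plvap, a component of endothelial fenestrae, read 8.61 ± 0.31 (SD, n = 3) in dB/dB and 6.48 ± 0.72 in wild type, a difference of 2.13 (log2, SE 0.61), higher in 3 of 3 arrays. Slc26a4, the pendrin exchanger of intercalated cells, differed by 2.92 (SE 0.94), and Calb1, the calcium-binding protein of the distal convoluted tubule, by 1.66 (SE 0.70). Mvd, of the mevalonate pathway, differed by -1.27 (SE 0.57) and Fasn, the fatty acid synthase, by -1.07 (SE 0.51). Each of these 5 genes had an adjusted p of 0.767, short of the threshold.

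As lists, 9 of 32 were called by camera in dB/dB against wild type, 8 upward and 1 downward, and 0 with an estimated correlation. All 16 endothelial markers were above 0, with a median of 1.45 (adjusted p = 7.17e-08, and adjusted p = 0.628 with an estimated correlation). Collecting duct markers had a median of 1.42 over 10 genes, loop of Henle and distal tubule markers 1.21 over 14, and fibroblast and mural markers 1.45 over 9, each with adjusted p = 0.628 with an estimated correlation. Podocyte markers had a median of 0.79 over 9 genes (adjusted p = 0.0287, and adjusted p = 0.861 with an estimated correlation). Beside these marker lists stood fibrosis and matrix genes (median 0.36 over 20, Ccn2 at 2.23 with SE 1.27; adjusted p = 0.808 with an estimated correlation) and tubular injury genes (median 0.17 over 22, Lgals3 at 1.87 with SE 0.86; adjusted p = 0.628 with an estimated correlation). Immediate early and heat shock genes had a median of 0.62 over 21 genes, adjusted p = 0.861 with an estimated correlation, and of the 3 members of smallest p, Dusp1, a phosphatase of MAP kinases, lay at 1.06 (SE 0.75), while the chaperones Hsph1 at -0.84 (SE 0.39) and Dnajb1 at -0.29 (SE 0.20) went the other way. Lipid and sterol synthesis was the list called downward, with 22 of 25 genes below 0 and a median of -0.39 (adjusted p = 0.00762, and adjusted p = 0.628 with an estimated correlation). No member of any list passed, either over all probe sets or adjusted over the list alone. Without wild type 2, the fibrosis (adjusted p = 0.153), loop and distal tubule (0.104), immediate early (0.745) and podocyte (0.274, with its direction turned) calls ended. Wild type 3 and dB/dB 2 each ended the immediate early call (0.0605 and 0.0713), and dB/dB 3 the podocyte call (0.324).

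Among single probe sets, limma called 0 of 18144 in dB/dB against wild type, with 755 at an unadjusted p under 0.05 where 907.2 would arise by chance. The lowest adjusted p was 0.363. The median change of all probe sets was -0.11, which centring the arrays on their medians takes out. Bmf, a pro-apoptotic member of the Bcl-2 family, read 5.62 ± 0.21 (SD, n = 3) in dB/dB and 4.36 ± 0.59 in wild type, a difference of 1.26 (SE 0.31, adjusted p = 0.767). Outside dB/dB it lay near the filter of 4 on most arrays, with the same value of 4.286 on catalase-Tg 3 and dB/dB catalase-Tg 2. Its other probe sets were below the filter, so background may limit the differences of Bmf. Agt, angiotensinogen, read 4.59 ± 0.19 and 6.09 ± 2.10, and its -1.49 (SE 0.93, adjusted p = 0.767) did not pass. Both passed without wild type 1, catalase-Tg 1 and dB/dB catalase-Tg 1 (adjusted p = 0.00323 for Bmf and 0.00172 for Agt), and over all alternatives their adjusted p ran from there to 1. Kap read 13.36 ± 0.50 in dB/dB and 11.85 ± 3.30 in wild type, and its 1.504 (SE 1.89, adjusted p = 0.795) became -0.11 without wild type 1. Casp12, the endoplasmic reticulum caspase, had group means of 2.39 to 3.32 and Tgfb1, transforming growth factor beta 1, of 2.35 to 2.98, both under the filter and not tested. The count of 0 rose to 107 without wild type 1, and to 4875 without wild type 1, catalase-Tg 1 and dB/dB catalase-Tg 1. For the 4875 as for Bmf and Agt, that fit leaves wild type with wild type 2 and wild type 3. These are the arrays that carry Xist, a transcript of female cells (11.9 and 6.72), so sex may differ between the groups compared. With no filter the count was 6.

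In mice without the mutation, the transgene comparison of catalase-Tg with wild type asks what the transgene does by itself. Angptl7, a secreted angiopoietin-like protein, rose from 2.49 ± 0.01 (SD, n = 3) near the floor to 8.32 ± 1.03, a difference of 5.83 (log2, SE 0.39, adjusted p = 0.000451). Fkbp1b, an immunophilin that binds ryanodine receptors, rose by 2.47 (SE 0.22, adjusted p = 0.00317) from 2.51 to 4.99. Wild type lay below the filter of 4 and near the floor for both genes, so these sizes are limited by background. All the tests with 12 arrays assume 1 spread for every group, while Angptl7 had an SD of 0.01 in wild type and 1.03 in catalase-Tg. Its SE and p-values may therefore be too small. Med1, a subunit of the Mediator coactivator complex, fell from 8.01 ± 0.03 to 6.14 ± 0.17, a change of -1.87 (SE 0.21, adjusted p = 0.0146). A probe set without a gene symbol changed by -3.51 (SE 0.34, adjusted p = 0.00502). Each change was seen in 3 of 3 arrays. These were the 4 probe sets called, 2 higher and 2 lower, with 1660 at an unadjusted p under 0.05. Without wild type 2 the count was 270, and without wild type 1 it was 7. Med1 lost its call without any 1 of wild type 3, catalase-Tg 1, catalase-Tg 2 and catalase-Tg 3 (adjusted p = 0.0757, 0.0563, 0.0883 and 0.0647). On a second bright Med1 probe set the groups overlapped, at 6.58 to 7.38 in wild type and 6.42 to 6.88 in catalase-Tg. With the 6 arrays of these groups alone in limma 0 were called (adjusted p = 0.184 for Angptl7, Fkbp1b and Med1), and with no filter 14. Over all alternatives the adjusted p of Med1 ran from 0.00367 to 0.184. Without wild type 2 and wild type 3, 2180 were called.

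Among the lists of catalase-Tg against wild type, markers of other nephron segments and of glomerular cells lay lower and proximal tubule genes higher. Podocyte markers had a median of -2.84 over 9 genes, with 7 lower when adjusted over the list alone, and loop and distal tubule markers a median of -2.00 over 14, with 9 lower when adjusted over the list alone (both adjusted p = 0.714 with an estimated correlation). Nphs1, the slit diaphragm protein nephrin, differed by -2.61 (SE 0.98), and Slc12a1, the salt cotransporter of the thick ascending limb, by -2.54 (SE 0.69). Endothelial markers had a median of -1.32 over 16. Proximal tubule genes had a median of 0.85 over 36 (adjusted p = 8.8e-06, and adjusted p = 0.714 with an estimated correlation; 0.546 without wild type 1, and 8.67e-15 to 0.987 over all alternatives), among them the phosphate transporter Slc34a1 at 0.53 (SE 0.21), while Mme, neprilysin, lay at -2.28 (SE 0.60). Male-enriched and androgen-responsive genes had a median of 2.14 over 10, with Cyp4a12a, a fatty acid hydroxylase, at 4.48 (SE 1.83; adjusted p = 0.714 for the list with an estimated correlation). Their scores were -3.01, -1.29 and 2.83 on wild type 1, 2 and 3 and -1.47, 3.13 and 3.37 on catalase-Tg 1, 2 and 3, and wild type 2 carries Xist at 11.9, a transcript of female cells, with Y-linked Eif2s3y at the floor. That call ended without wild type 1 (adjusted p = 0.258), catalase-Tg 2 (0.0737) or catalase-Tg 3 (0.0985), in a range of 1.56e-06 to 0.714 over all alternatives. Peroxisomal genes other than catalase had a median of 0.24 over 31. NRF2 targets had a median of 0.45 over 21, yet Gsta4, a glutathione transferase, lay at -1.62 (SE 0.49) and Hmox1, heme oxygenase 1, at 1.14 (SE 0.48). Fibrosis genes (median -0.62 over 20, Col5a2 at -5.14 with SE 1.12), tubular injury genes (-1.06 over 22, S100a10 at -1.01 with SE 0.23) and interferon and antigen presentation genes (-1.06 over 21, Ifit2 at -1.82 with SE 0.36) had 1 member lower each when adjusted over the list alone. In all, camera called 10 lists, 4 upward and 6 downward, each with adjusted p = 0.714 with an estimated correlation, and 21 members passed adjusted over the list alone against 0 over all probe sets. The number of lists was 2 without wild type 1, 18 without wild type 2, 17 without catalase-Tg 1, and 3 without catalase-Tg 2 or without catalase-Tg 3. Only the podocyte and loop and distal tubule calls stood without any 1 of the 6 arrays.

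**Figure D2:**
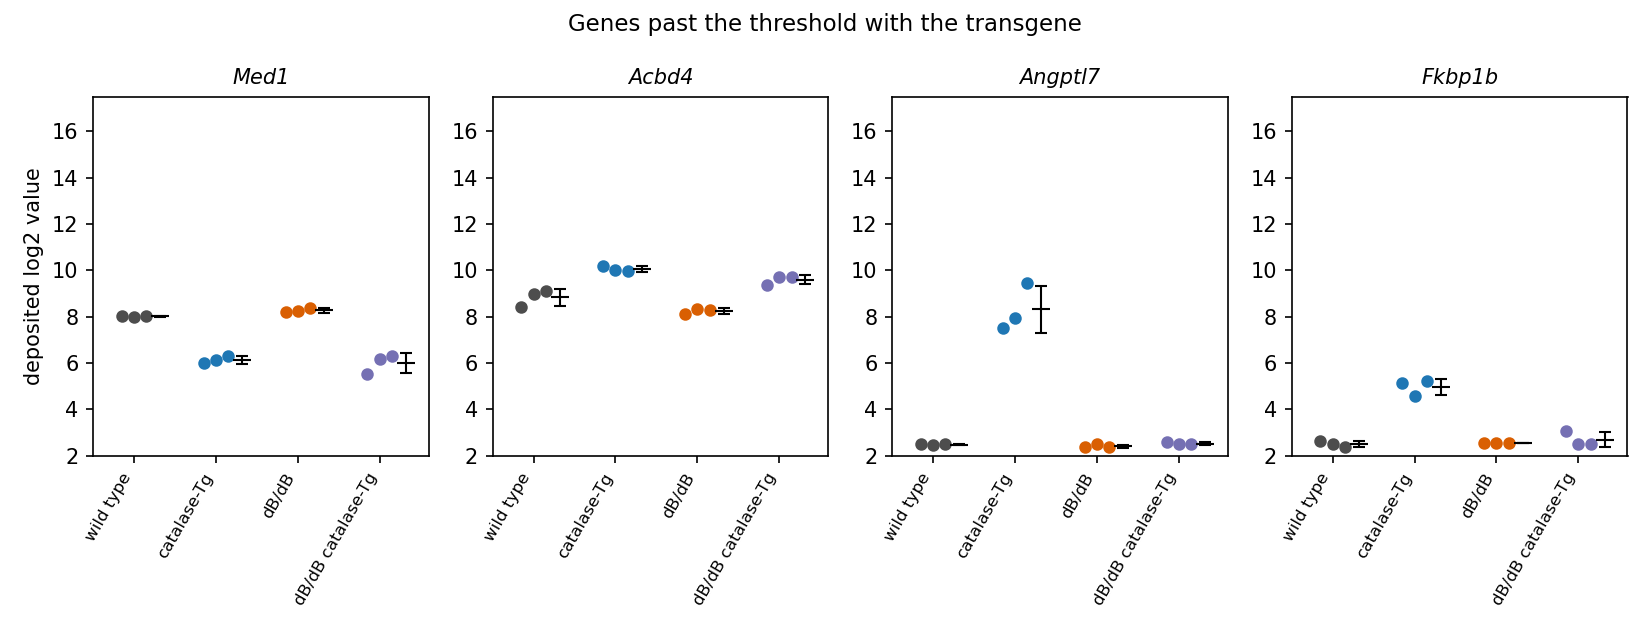
Deposited log2 value of 4 genes past the threshold in a transgene contrast, 1 point per array, with the mean and SD of each group of 3 beside it. Med1, on its brightest probe set only, reads 8.01 and 8.28 without the transgene and 6.14 and 6.01 with it. Angptl7 and Fkbp1b average 8.32 and 4.99 in catalase-Tg and no more than 2.53 and 2.70 in the other groups, below the filter of 4.

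The study's central comparison, dB/dB catalase-Tg against dB/dB, asks what the transgene does in diabetic mice. Med1 fell from 8.28 ± 0.10 (SD, n = 3) to 6.01 ± 0.42, a change of -2.27 (log2, SE 0.21, adjusted p = 0.00974), lower in 3 of 3 arrays. Bmf read 4.60 ± 0.48 with the transgene and 5.62 ± 0.21 without, and its -1.02 (SE 0.31, adjusted p = 0.636) did not pass. Agt differed by 1.46 (SE 0.93, adjusted p = 0.642), Hmox1 by 0.81 (SE 0.48, adjusted p = 0.636) and Kap by 0.96 (SE 1.89, adjusted p = 0.867). Bmf, Agt and Hmox1 did pass with array weights (adjusted p = 0.00191, 0.00373 and 0.0113) and without wild type 1, catalase-Tg 1 and dB/dB catalase-Tg 1 (0.00489, 0.0027 and 0.0409), and with the other-cell marker score as a covariate each had the highest adjusted p of its alternatives, 1.00. Med1 was the 1 probe set called, with 1360 at an unadjusted p under 0.05, and 0 were called without any 1 of dB/dB 1, dB/dB 2, dB/dB 3 and dB/dB catalase-Tg 2 (adjusted p of Med1 = 0.091, 0.0887, 0.118 and 0.0573). A second bright Med1 probe set, of mean 6.67, did not show the fall: over both dB/dB states it differed by -0.23 (SE 0.27). Array weights brought the count to 6989, with the low weights of 0.227 for wild type 1, 0.287 for catalase-Tg 1 and 0.172 for dB/dB catalase-Tg 1, and leaving those 3 arrays out gave 5043. Adding the score of other-cell markers to the weighted fit left 1, and with no filter the count was 3. With the 6 arrays alone it was 2, Med1 not among them (adjusted p = 0.225), and over all alternatives the adjusted p of Med1 ran from 7.63e-05 to 0.225.

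Proximal tubule genes as a list had a median difference of 0.87 between dB/dB catalase-Tg and dB/dB, with 35 of 36 above 0 (adjusted p = 5.94e-07, and adjusted p = 0.707 with an estimated correlation). Only dB/dB catalase-Tg 2 and 3, with scores of 0.80 and 0.82, lay above dB/dB (-0.73 to -0.38), and dB/dB catalase-Tg 1 at -0.55 lay within it. Fatty acid oxidation and peroxisomal scores on that array, -0.58 and -0.65, lay within the dB/dB arrays and below them. Slc5a12, a lactate transporter, differed by 1.43 (SE 0.54). Fatty acid oxidation genes had a median of 0.48 over 31, with Angptl4, a PPAR target, at 1.76 (SE 0.95), and peroxisomal genes a median of 0.39 over 31, with Acox2, a peroxisomal oxidase, at 2.52 (SE 1.35). Antioxidant enzymes other than catalase had a median of 0.21 over 19, with Txn1, thioredoxin, at 0.72 (SE 0.29) and the extracellular superoxide dismutase Sod3 at 1.55 (SE 0.70), while Gpx8 lay at -1.92 (SE 0.89). NRF2 targets had a median of 0.50 over 21, with Gsta4 at -1.42 (SE 0.49), and male-enriched genes a median of 1.18 over 10. Markers of other cells had medians below 0, with scores lower than in every dB/dB array on dB/dB catalase-Tg 2 and 3 but not on dB/dB catalase-Tg 1 (podocyte 0.82, endothelial 1.55, mural 1.56): podocyte -2.46 over 9, with the podocyte phosphatase Ptpro at -3.19 (SE 1.36), endothelial -1.58 over 16, with the tight junction protein Cldn5 at -2.81 (SE 1.22), and fibroblast and mural -1.66 over 9, with Pdgfra at -2.42 (SE 0.82). Fibrosis genes had a median of -0.65 over 20, with Ccn2, connective tissue growth factor, at -2.98 (SE 1.27), and immediate early genes -0.41 over 21. These 11 lists, 6 upward and 5 downward, were called by camera, each with adjusted p = 0.707 with an estimated correlation, and 0 members passed either over all probe sets or adjusted over the list alone. Leaving out 1 array ended 5 of the calls: fatty acid oxidation without dB/dB catalase-Tg 3 (adjusted p = 0.076), mural without dB/dB catalase-Tg 2 (0.0737), antioxidant enzymes without dB/dB 3, dB/dB catalase-Tg 2 or dB/dB catalase-Tg 3 (0.0635, 0.0618 and 0.0659), male-enriched genes without dB/dB 1, dB/dB catalase-Tg 1 or dB/dB catalase-Tg 2 (0.0891, 0.0716 and 0.113), and immediate early genes without dB/dB 2, dB/dB catalase-Tg 2 or dB/dB catalase-Tg 3 (0.312, 0.198 and 0.715). With the other-cell marker score as a covariate, 14 of the 30 list calls of these 3 comparisons turned direction and 12 more ended. The covariate is built from the podocyte, endothelial and mural lists, so for those lists that outcome is fixed in part.

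**Figure D3:**
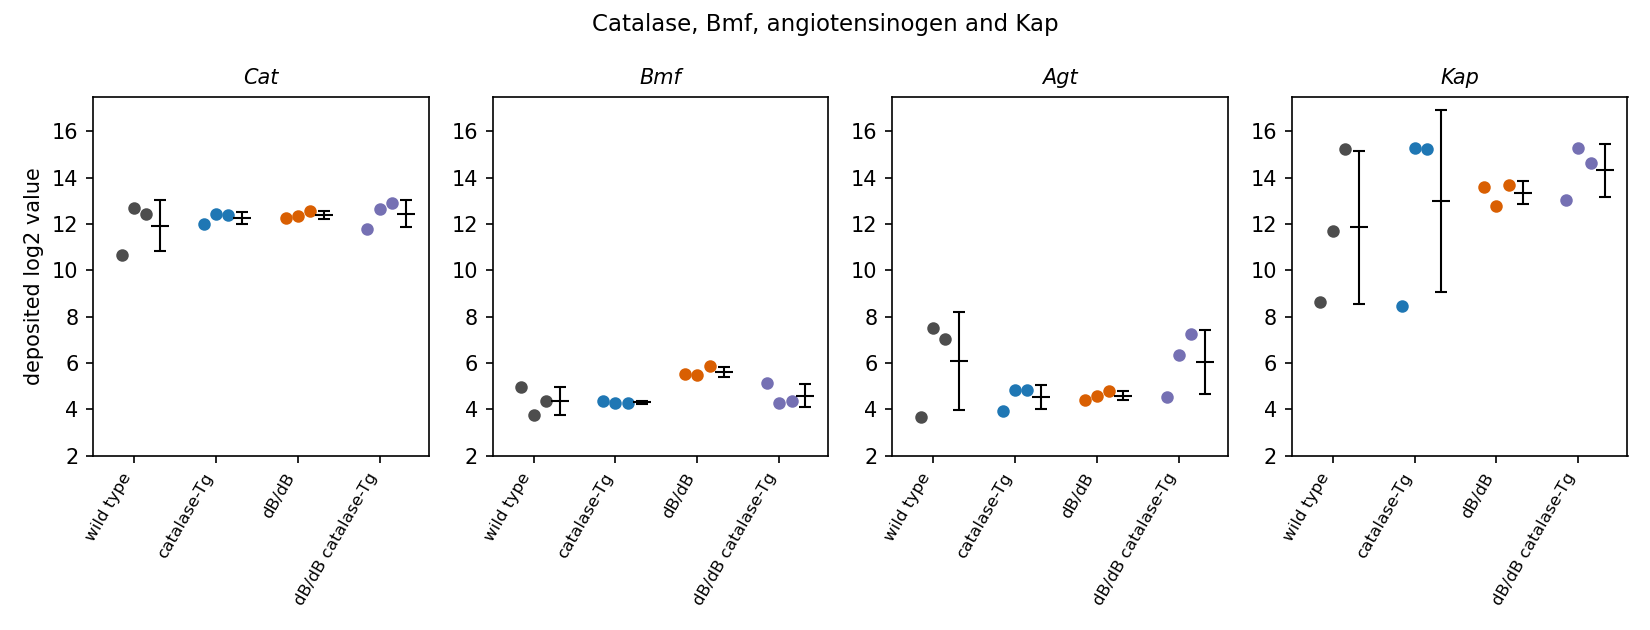
Deposited log2 value of Cat, Bmf, Agt and Kap, 1 point per array, with the mean and SD of each group of 3 beside it. Bmf reads 5.62 in dB/dB and between 4.31 and 4.60 in the other groups, and no difference among the 4 genes passed the threshold with all 12 arrays at equal weight.

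Genes changed by dB/dB and moved back by the transgene would answer the study's question most directly. Limma found 0 probe sets past the threshold in both contrasts with opposite directions. At an unadjusted p under 0.05 there were 233, 120 of them up in dB/dB and 113 down. Both contrasts hold the dB/dB arrays, and 100 simulations of unchanged groups gave 225.18 on average and 258 at most, against 23.1 for independent lists. The simulations gave a probe set the same spread in all groups. On the axis along which the arrays varied most, the SD was 2.57 in dB/dB, against 84.7 in wild type, 32.2 in catalase-Tg and 67.6 in dB/dB catalase-Tg. Sharing may therefore add less than simulated, and the simulations cannot settle how much of the 233 it explains. Across probe sets, which are not independent replicates, the correlation of the contrasts was -0.788 against -0.498 in the simulations, and the covariance -0.249 against -0.111. The dB/dB arrays were not split between the contrasts, so part of these values may come from sharing. The count was 2 without wild type 1, 1 with no filter, and 3523 without wild type 1, catalase-Tg 1 and dB/dB catalase-Tg 1. That last fit leaves wild type with wild type 2 and wild type 3, the arrays that carry Xist.

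Among transgenic mice, dB/dB catalase-Tg against catalase-Tg shows the mutation on the second background. Angptl7 fell by 5.79 (log2, SE 0.39, adjusted p = 0.000485) and Fkbp1b by 2.28 (SE 0.22, adjusted p = 0.00686). Both fell to values below the filter of 4 and near the floor, at 2.53 and 2.70, so background limits these sizes. Ang, the ribonuclease angiogenin, fell from 5.73 ± 0.49 (SD, n = 3) to 2.76 ± 0.06, a change of -2.97 (SE 0.37, adjusted p = 0.038). 1700028P14Rik changed by -2.40 (SE 0.27, adjusted p = 0.0224) and a probe set without a symbol by -1.77 (SE 0.22, adjusted p = 0.038). Ang also lay near the floor in dB/dB catalase-Tg, so background limits its size too. 1700028P14Rik averaged 3.604 there, below the filter of 4 but above the floor (4.00, 3.29 and 3.52 on the 3 arrays). Background may limit that size as well. These 5 were the probe sets called, all lower in 3 of 3 arrays, with 1245 at an unadjusted p under 0.05. With the 6 arrays of these groups alone in the fit, 6 probe sets were called, all higher: none of the 5 passed there, Angptl7 having an adjusted p of 0.0583, Ang 0.069, 1700028P14Rik 0.0704 and Fkbp1b 0.0878. The Ang call also ended without any 1 of the 6 arrays (adjusted p up to 0.246), that of 1700028P14Rik without any 1 but dB/dB catalase-Tg 1 (0.0826 to 0.202), and that of Fkbp1b without catalase-Tg 3, dB/dB catalase-Tg 2 or dB/dB catalase-Tg 3 (up to 0.0712). The count was 2 without catalase-Tg 2, 3 without dB/dB catalase-Tg 1, and 1 without catalase-Tg 3, dB/dB catalase-Tg 2 or dB/dB catalase-Tg 3. It was 1 with the stricter filter or with arrays centred on their medians, 3 after quantile normalization, 883 with array weights, 23 without the 3 arrays of low weight and 174 without wild type 2 and wild type 3. Camera called 12 lists, all upward, 0 of them with an estimated correlation (lowest adjusted p = 0.263), and 15 members passed adjusted over the list alone against 0 over all probe sets. Loop and distal tubule markers had a median of 2.12 over 14, with 9 higher adjusted over the list alone, and tubular injury genes 0.91 over 22, with 4 higher. Beside them stood collecting duct markers (1.49 over 10), interferon and antigen presentation genes (1.06 over 21), endothelial markers (1.13 over 16), podocyte markers (1.52 over 9) and glycolysis (0.41 over 12). Without dB/dB catalase-Tg 1 the number of lists was 6, and the tubular injury (adjusted p = 0.0693), interferon (0.151), endothelial (0.521) and podocyte (0.532) calls were among those that ended, the highest p over all alternatives being 0.29, 0.71, 0.80 and 0.932. That array scored 2.76 on interferon and 1.55 on endothelial genes, and the other 2 of its group -0.29 and -0.90, and -0.82 and -1.18.

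Averaged over both transgene states, Rgcc, a regulator of the cell cycle, rose by 2.26 (log2, SE 0.24, adjusted p = 0.0217) with dB/dB. It read 7.11 ± 0.35 and 6.42 ± 0.36 (SD, n = 3 each) in the dB/dB groups and 4.87 ± 0.55 and 4.14 ± 0.49 in the others, higher in 6 of 6 arrays. Angptl7 (-2.93) and 1700028P14Rik (-1.62) were the others of 3 called, with 2206 at an unadjusted p under 0.05, and both averages rest largely on the catalase-Tg group. Loop and distal tubule markers had a median of 1.75 over 14, collecting duct markers 1.60 over 10 and endothelial markers 1.28 over 16, among 12 lists called upward. None of the 12 was called with an estimated correlation (lowest adjusted p = 0.356), and 29 members passed adjusted over the list alone against 0 over all probe sets. The Rgcc call ended without any 1 of 8 arrays (adjusted p = 0.0517 to 0.131), as did that of 1700028P14Rik (up to 0.191), and that of Angptl7 without any 1 of 4 (up to 0.0836). The count was 1246 without wild type 1, 6 without wild type 2, 1 without catalase-Tg 2 or without catalase-Tg 3, and 0 without dB/dB 1, dB/dB 2, dB/dB 3 or dB/dB catalase-Tg 2. With the other-cell marker score as a covariate it was 0, without wild type 2 and wild type 3 it was 0, and with array weights 1975.

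Averaged over both dB/dB states, Med1 on its brightest probe set fell by 2.07 (log2, SE 0.15, adjusted p = 0.000801), lower in 6 of 6 transgenic arrays. Its second bright probe set did not show the fall (-0.23, SE 0.27, adjusted p = 0.679). Acbd4, an acyl-CoA-binding protein, rose by 1.29 (SE 0.14, adjusted p = 0.0169), from 8.83 ± 0.35 to 10.06 ± 0.11 (SD, n = 3 each) without dB/dB and from 8.25 ± 0.12 to 9.61 ± 0.19 with it, higher in 6 of 6, and its second probe set differed by 1.91 (SE 0.43). The probe set without a symbol that fell in catalase-Tg changed by -2.07, Angptl7 by 2.97 and Fkbp1b by 1.32. These 3 rest largely on the catalase-Tg group: the probe set without a symbol went from 7.65 to 4.14 without dB/dB and from 6.67 to 6.04 with it. These were the 5 called, with 3287 at an unadjusted p under 0.05. Podocyte markers had a median of -2.70 over 9, all 9 lower adjusted over the list alone, and proximal tubule genes 0.81 over 36, among 12 lists called, 6 upward and 6 downward. None was called with an estimated correlation (lowest adjusted p = 0.709), and 30 members passed adjusted over the list alone against 0 over all probe sets. The proximal tubule list turned direction in 1 of 20 alternatives, and its camera adjusted p reached 0.983 with the other-cell marker score as a covariate. The Acbd4 call ended without any 1 of 8 arrays (adjusted p = 0.0566 to 0.0994) and with the other-cell marker score as a covariate, where Acbd4 shrank to 1.10 (SE 0.17, adjusted p = 0.251) and Med1 was -2.25 (SE 0.18, adjusted p = 0.00384). Med1 was the only probe set called with the covariate, which also ended the Angptl7 and Fkbp1b calls (adjusted p = 0.0919 each). Over all alternatives the adjusted p ran from 0.000631 to 0.251 for Acbd4, from 3.33e-05 to 0.00744 for Med1 and from 4.99e-05 to 0.0919 for Angptl7. The Fkbp1b call ended without any 1 of 8 arrays (adjusted p up to 0.1, the highest of its alternatives). The count was 4785 with array weights, 1 with the covariate, 969 without wild type 2, 8 without wild type 1 or without dB/dB catalase-Tg 1, 3 without catalase-Tg 1, catalase-Tg 2 or dB/dB catalase-Tg 3, 2 without catalase-Tg 3, dB/dB 1, dB/dB 2, dB/dB 3 or dB/dB catalase-Tg 2, and 5 without wild type 3.

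Whether the transgene effect differed between diabetic and other mice was tested as an interaction. Angptl7 differed by -5.71 (log2, SE 0.55, adjusted p = 0.0163): it rose with the transgene in all 3 catalase-Tg arrays and read 2.53 ± 0.06 (SD, n = 3) in dB/dB catalase-Tg. In 3 of the 4 groups Angptl7 lies below the filter of 4, so the size of this difference is limited by background. The test assumes 1 spread for all groups, while the SD was 1.03 in catalase-Tg and 0.01, 0.07 and 0.06 in wild type, dB/dB and dB/dB catalase-Tg. Its p-value may therefore be too small. It was the 1 probe set called, with 297 at an unadjusted p under 0.05. Fkbp1b differed by -2.31 (SE 0.31, adjusted p = 0.15), and the next genes by p, Klhdc8a at 1.68, Akr1e1 at 2.62 and the peroxisomal reductase Decr2 at 1.40, each had an adjusted p of 1. The fall of Med1 differed by -0.39 (SE 0.29, adjusted p = 1) between the dB/dB states. The Angptl7 call ended without wild type 1 (adjusted p = 0.0732), wild type 2 (0.0793), catalase-Tg 2 (0.0557) or any 1 of the 6 dB/dB arrays (0.0627 to 0.11). Without wild type 3 the count was 2. Camera called 5 lists upward, among them loop and distal tubule markers (median 0.96 over 14) and interferon and antigen presentation genes (0.88 over 21), each with adjusted p = 0.996 with an estimated correlation. The interferon call rests on dB/dB catalase-Tg 1, which scored 2.76 against -0.29 and -0.90 on the other 2 arrays of its group: without it the list turned direction (adjusted p = 0.567, in a range up to 0.999 over all alternatives). The loop and distal tubule call ended without it (0.161) or without wild type 1 (0.21), in a range up to 0.999, and that list turned direction in 1 of 20 alternatives. No list member passed over all probe sets or adjusted over the list alone. The number of lists was 11 without wild type 1, 3 without catalase-Tg 2, dB/dB 2 or dB/dB 3, and 2 without dB/dB catalase-Tg 3.

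The mutation's effect with and without the transgene correlated at 0.642 across probe sets, from contrasts that share no array, and the transgene's effect with and without dB/dB at 0.725. Both are across probe sets, which are not independent replicates. Probe sets with the same sign made up 72.1% in either pair. The first value was 0.236 without dB/dB catalase-Tg 1 and 0.422 without wild type 2, and it turned to -0.27 without wild type 2 and wild type 3. The second was 0.344 without wild type 1. With the other-cell marker score as a covariate the values were 0.369 and 0.49.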

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

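The results below differ between diabetic and other mice by a test of the interaction, and that test and the division of the samples into other groups were chosen before the data were examined. Angptl7 differed by -5.71 (log2, adjusted p = 0.0163) between the transgene effect with and without dB/dB, since it rose in all 3 catalase-Tg arrays and in 0 of the 3 dB/dB catalase-Tg arrays. The test assumes 1 spread for all groups, but all except catalase-Tg lie near the floor with little spread, so this p-value may be too small. The Angptl7 call ended in 9 of the 12 fits that left out 1 array (adjusted p up to 0.11). Camera called 5 lists higher in the interaction, with medians of 0.96 for loop of Henle and distal tubule markers, 0.88 for interferon and antigen presentation genes, 0.37 for fatty acid oxidation, 0.32 for glycolysis and 0.29 for lipid and sterol synthesis. Each had an adjusted p of 0.996 with an estimated correlation. The interferon list turned direction without dB/dB catalase-Tg 1 (adjusted p = 0.567, in a range up to 0.999 over all alternatives), an array that scored 2.76 where the other 2 of its group scored -0.29 and -0.90, so for this list the difference is that of 1 array. Each of the other 4 calls also ended without 1 array or more, and the loop and distal tubule and fatty acid oxidation lists each turned direction in 1 of 20 alternatives.

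The 12 arrays were also divided into other groups of 3, without regard to replicate number. For the interaction, 10 of 100 divisions called at least the 1 probe set found, and 89 of 100 called at least its 5 lists, so chance is excluded for neither. A division that called 7649 probe sets points to a structure of the arrays that crosses the groups. For the average dB/dB effect 3 of 100 divisions, the real one included, called at least the 3 probe sets found (highest other 6). That share lies under 0.05 but was not adjusted over the counts compared, so chance is not excluded. At least the 12 lists were called in 45 of 100 (highest other 18). For the average transgene effect 3 of 100 called at least the 5 probe sets, with the same limit. Another division called 5447, again a structure of the arrays, and 40 of 100 called at least the 12 lists (highest other 17).

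With 3 arrays against 3 there are 10 divisions, too few for a share under 0.05. For dB/dB against wild type the real count was 0 (as many in 10 of 10, highest other 74) with 9 lists (8 of 10, highest other 16). For catalase-Tg against wild type it was 4 (2 of 10, highest other 30) with 10 lists (7 of 10, highest other 18). For dB/dB catalase-Tg against dB/dB it was 1 (2 of 10, highest other 1) with 11 lists (4 of 10, highest other 15). For dB/dB catalase-Tg against catalase-Tg it was 5 (1 of 10, highest other 0) with 12 lists (3 of 10, highest other 16). The divisions calling 74 and 30 probe sets, against 0 and 4, point to the same structure.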

How the results depend on the processing

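The fits with the other-cell covariate, with sets of arrays left out and with array weights in the list test were chosen after the results were seen. Where the cause of a move is not named, the cause was not tested. In a fit that leaves a group with 1 array, that array is assumed to vary like the other groups.

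Counts of probe sets are given in the order dB/dB against wild type, catalase-Tg against wild type, dB/dB catalase-Tg against dB/dB, dB/dB catalase-Tg against catalase-Tg, interaction, average dB/dB effect and average transgene effect. They were 0, 4, 1, 5, 1, 3 and 5. Leaving out 1 array gave 0 to 107, 3 to 270, 0 to 1, 1 to 5, 0 to 2, 0 to 1246 and 2 to 969, with 0 to 2 moved back. Without wild type 1, catalase-Tg 1 and dB/dB catalase-Tg 1 they were 4875, 31, 5043, 23, 143, 3515 and 3711, with 3523 moved back. In that fit wild type consists of wild type 2 and wild type 3, the arrays that carry Xist. Without wild type 2 and wild type 3 catalase-Tg against wild type gave 2180, dB/dB catalase-Tg against catalase-Tg 174, the interaction and the average dB/dB effect 0 each, and the average transgene effect 3375. Array weights gave 6989 for dB/dB catalase-Tg against dB/dB, 883 for dB/dB catalase-Tg against catalase-Tg, 1975 for the average dB/dB effect and 4785 for the average transgene effect. With no filter dB/dB against wild type gave 6, catalase-Tg against wild type 14, dB/dB catalase-Tg against dB/dB 3, the interaction 6, the averages 5 and 9, and 1 was moved back. With the groups of the contrast alone, catalase-Tg against wild type gave 0 and dB/dB catalase-Tg against dB/dB 2. In dB/dB catalase-Tg against catalase-Tg that fit gave 6, close to 5 in number, but all 6 were higher where the 5 were all lower, so the similar count hides different probe sets. That contrast gave 1 with the stricter filter, 3 after quantile normalization and 1 with arrays centred, and centring gave 3 for the average transgene effect. The average dB/dB effect gave 5 with 1 probe set per gene. Replicate number as a block gave 0 for the interaction, with Angptl7 at an adjusted p of 0.0527, and 1 for the average dB/dB effect, with Rgcc and 1700028P14Rik at 0.0846 each. The labels do not say whether equal numbers belong together. Residuals of the 18 same-number pairs correlated at -0.18 to 0.71 (median 0.209, against -0.0895 for other pairs), 13 of them over 0.1. All 9 pairs among wild type, catalase-Tg and dB/dB catalase-Tg were over 0.1 (0.200 to 0.705), and the 5 that were not each hold a dB/dB array. Not every sample correlated best with its own number, wild type 2 going with catalase-Tg 3 at 0.241 and with catalase-Tg 2 at 0.200. These values are a hint from the data, not the design, that numbers go together in 3 groups, and since this did not hold for every pair the samples were not taken as paired. With the other-cell covariate the averages gave 0 and 1.

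The correlation of the dB/dB effects, 0.642, ran from 0.236 to 0.736 with 1 array left out, and was 0.369 with the covariate, 0.492 without the 3 arrays and -0.27 without wild type 2 and wild type 3. That of the transgene effects, 0.725, ran from 0.344 to 0.798, and was 0.49 with the covariate and 0.546 without the 3 arrays.

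The brighter Cat probe set turned to -0.17 in dB/dB against wild type and -0.15 in catalase-Tg against wild type without the 3 arrays, and to -0.39 in catalase-Tg against wild type and -0.73 in dB/dB catalase-Tg against dB/dB with the covariate. It was 1.60 in catalase-Tg against wild type without wild type 2 and wild type 3, where it passed (adjusted p = 0.0403, in a range up to 1). Leaving out 1 array gave -0.17 to 0.84, -0.29 to 0.72 and -0.17 to 0.39 in these 3 contrasts. The second Cat probe set, -0.04 in dB/dB against wild type, turned to 0.0565 after quantile normalization, 0.0794 with centring, 0.59 with the covariate and 1.35 without wild type 2 and wild type 3, and was -0.73 without the 3 arrays, where it passed (adjusted p = 0.0383, in a range up to 1). The covariate turned it to -0.47 in catalase-Tg against wild type and to -0.30 in dB/dB catalase-Tg against dB/dB, where it was 0.98 with array weights and 1.10 without the 3 arrays and passed in both (adjusted p = 0.0121 and 0.00945, in a range up to 1.00). Leaving out 1 array gave -0.73 to 0.46, -0.25 to 0.94 and 0.47 to 1.10.

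Other genes changed direction, and none passed in the turned direction. Bmf in catalase-Tg against wild type, -0.05, turned to 0.083 with array weights, 0.0415 after quantile normalization, 0.0159 with centring, 0.48 with the covariate and 0.22 without the 3 arrays, and ran from -0.35 to 0.25 with 1 array left out. Kap in dB/dB against wild type turned to -0.11 without the 3 arrays, with a range of -0.11 to 3.19. With the covariate Kap turned to -0.35 in catalase-Tg against wild type (range -0.48 to 3.39) and to -0.64 in dB/dB catalase-Tg against dB/dB. The covariate also turned Agt to -0.19, Odc1 to -0.037, Hspa1b to 0.12 and Klf4 to 0.30 in dB/dB catalase-Tg against dB/dB, Ccn2 to 0.0584 in catalase-Tg against wild type, and Cdkn1c to -0.0321, Podxl to -0.45 and Ptpro to -0.29 in dB/dB against wild type. With 1 array left out those last 3 ran from -0.28 to 2.38, -0.37 to 2.31 and -0.51 to 2.38. Leaving out wild type 2 and wild type 3 turned Agt to 0.86 in catalase-Tg against wild type. In dB/dB against wild type the same fit turned Agt to 0.91, Hmox1 to 0.21, Mvd to 0.39, Fasn to 0.13, Ccn2 to -0.30, Lamb1 to -0.0584, Bgn to -0.073, Lgals3 to -0.30, Clu to -0.65, Dusp1 to -0.57, Slc12a3 to -0.17, Cdkn1c to -0.52, Podxl to -0.84, Ptpro to -0.84, Col1a2 to -0.69 and Myh11 to -0.15.

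The numbers of lists called were 9, 10, 11, 12, 5, 12 and 12 in the order of the counts. An estimated correlation gave 0 in each of the 7, and so did fry. Leaving out 1 array gave 8 to 12, 2 to 18, 8 to 16, 6 to 16, 2 to 11, 10 to 16 and 10 to 16. The covariate gave 5 in catalase-Tg against wild type, 7 in dB/dB catalase-Tg against dB/dB and 5 in the average transgene effect. Without the 3 arrays dB/dB against wild type gave 15, dB/dB catalase-Tg against dB/dB 19 and the interaction 12. Leaving out wild type 2 and wild type 3 gave 18 in catalase-Tg against wild type and 15 in the interaction. With array weights dB/dB catalase-Tg against dB/dB gave 17 and the interaction 10, and with no filter the former gave 7.

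Called lists of the last 4 contrasts turned direction in at least 1 alternative. These were fibrosis, immediate early and mural in dB/dB catalase-Tg against catalase-Tg, and fatty acid oxidation, interferon and loop in the interaction. In the average dB/dB effect they were fibrosis, immediate early, oxidative phosphorylation and podocyte. In the average transgene effect they were proximal tubule, fatty acid oxidation, fibrosis, immediate early, peroxisome, endothelial and mural. Lists of the first 3 contrasts that turned are given with their adjusted p in the new direction. Without wild type 2 and wild type 3, in dB/dB against wild type, these were fibrosis 0.284, immediate early genes 1.47e-05, loop and distal tubule 0.0301, podocyte 0.153 and mural 0.85. With the covariate they were immediate early genes 0.249 and podocyte 0.0774 in that contrast, where the podocyte list ran from 0.000459 to 0.324 with 1 array left out. In catalase-Tg against wild type the covariate turned fibrosis 0.14, injury 0.913, interferon 0.913, peroxisome 0.336 and endothelial 0.0106. In dB/dB catalase-Tg against dB/dB it turned proximal tubule 0.965, fatty acid oxidation 0.802, fibrosis 0.388, immediate early genes 2.19e-06, peroxisome 0.841, endothelial 0.0229 and mural 0.488. The covariate is built from the podocyte, endothelial and mural lists and may also take up a true effect of the groups. Over the 30 list calls of these 3 contrasts, it turned 14, ended 12 and left 4.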

Other observations

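The tests in this part were chosen after the result was seen, apart from that of RNA degradation. Several genes varied widely between arrays of 1 group. Xist, the transcript of the inactive X chromosome, read 11.9 on wild type 2, 6.72 on wild type 3 and under 2.7 on the other 10 arrays. The Y-linked Eif2s3y was at the floor on wild type 2 and at 7.89 on wild type 3. Slco1a1, an androgen-dependent transporter, read 9.92 on wild type 3, 10.7 on catalase-Tg 2, 10.9 on catalase-Tg 3, 8.02 on dB/dB catalase-Tg 2 and 5.32 on dB/dB catalase-Tg 3. On dB/dB catalase-Tg 1 the antigen presentation genes Cd74 and H2-Aa read 12.4 and 12.7, and the interferon list scored 2.76. Fabp1, the liver fatty acid-binding protein, read 2.57 on wild type 1, 13.1 on wild type 2 and 11.26 to 12.02 on arrays 2 and 3 of both transgenic groups. Cyp4a14, a fatty acid hydroxylase, read 2.48 on wild type 1, 11.7 on wild type 2, 11.6 on dB/dB catalase-Tg 3 and 9.65 on dB/dB 3.

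The first axis of variation, 60.4% of the total, parts the arrays within 3 of the 4 groups: wild type 1 at 98.5 lies with dB/dB (61.7 to 66.8) and wild type 2 at -66.3 with catalase-Tg, while dB/dB catalase-Tg 1 lies at 70.8 and the other 2 arrays of its group at -47.0 and -45.6. The widest spread within a group was 1.30 times the widest difference between group means, which restates this split and leaves the part of the dB/dB genotype open. RNA degradation was tested by the 3' minus 5' control difference, the mean of the Gapdh and beta-actin controls. Its Pearson r with the axis was 0.200 and its Spearman rho 0.154 (permutation p = 0.542 and 0.636, r 0.334 without the 2 farthest arrays). These 2 controls did not go together. The Gapdh difference was highest on dB/dB 2 and dB/dB catalase-Tg 1 (0.61 and 0.38) and lowest on catalase-Tg 3 (-0.11). The beta-actin difference was lowest on wild type 1 (1.85) and highest on wild type 3 (2.50). Their mean can hide a trend of 1 control, so this test cannot decide and RNA degradation stays open. Podocyte and leukocyte scores parted by over 2 standard errors on 11 of 12 arrays. Yet 1 fixed mix of other cells need not shift both lists by equal log2 amounts, so that test cannot decide. On catalase-Tg 1 and dB/dB 2 the podocyte score (-2.27 and 0.49) was the lowest of its group and the leukocyte score (0.86 and 1.33) the highest. On wild type 1 and dB/dB catalase-Tg 1 both scores were the highest of their group. Cells of other types, in 1 mix or in varying mixes, stay open. On 7 of 12 arrays at least 5 of 6 marker scores lay on 1 side of the group mean, against 2.64 in shuffled scores (permutation p = 0.0114). Each list was shuffled by itself, so this shows that the lists moved together across arrays and not why. With the other-cell score as a covariate, 0.0143% of the probe sets called under array weights in dB/dB catalase-Tg against dB/dB were left, their median change falling from 0.91 to 0.28 while the SE grew from 0.22 to 0.315, though a covariate that follows the groups can also take up a true effect. Differences between mice in the same genes and an exchange of labels were not tested and stay open: Med1 reads as labelled for the transgene on wild type 1 (8.02) and dB/dB catalase-Tg 1 (5.54), and Rgcc lies at 5.48 and 6.06 there, but both genes were picked with these arrays in the fit. Whether equal numbers were prepared together also stays open and was not tested. Residuals of wild type 1 correlated with those of catalase-Tg 1 at 0.396 and of dB/dB catalase-Tg 1 at 0.705, and the latter 2 at 0.607. Those of dB/dB 1 correlated with these arrays at 0.165, -0.0859 and -0.0452.

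Med1 and Acbd4 differed with the transgene in both dB/dB states. The tables argue against cells of other types for Med1, which passed with the other-cell covariate at 1.09 times its change, and against a fall of all Med1 transcripts on the array, since the other bright Med1 probe set differed by -0.23. For Acbd4 such cells stay open: with the covariate its change shrank from 1.29 (SE 0.14) to 1.10 (SE 0.17), 0.852 of its size, and its call ended as the SE grew and the change shrank (adjusted p = 0.251, in a range of 0.000631 to 0.251 over all alternatives). A chromosome segment that goes with the transgene stays open and cannot be told apart from an effect of catalase. Med1, Acbd4 and Smarce1 were left out of its test, which took the 50 other named genes of smallest p. Of these, 8 lay on the chromosome of Med1 against 4.15 in random sets (permutation p = 0.0519), short of the threshold, and another chromosome held 9. Of the 2 Smarce1 probe sets past the filter, 1 differed by -1.17 (adjusted p = 0.106) and the other by -0.16.

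Xist on wild-type arrays fits RNA of a female mouse on wild type 2: of 5 Y-linked probe sets above 4 on the other arrays, 0 were at or above 4 there. The tables argue against cross-hybridization of a single probe set, since 3 of 3 Xist probe sets were above 4. Wild type 3 has both Xist and Y-linked signal, and a mixture of RNA on it stays open and was not tested. The labels give no sex, so sex may differ between the groups compared: without these 2 arrays catalase-Tg against wild type called 2180 probe sets and the 2 dB/dB effects correlated at -0.27, with the lone wild-type array left, wild type 1, being itself out of place on the first axis.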
